A study of Mus musculus with 3 samples.

How the data were processed

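Primary hepatocytes of wild-type mice were profiled by droplet single-cell RNA sequencing with a 3′ kit that tags each captured molecule with a unique molecular identifier (UMI), per the labels' protocols. Mice received a normal diet (ND), a 60% high fat diet (HFD), or that high fat diet with 0.25% of the bile acid hyodeoxycholic acid (HFD_HDCA) for 12 weeks, and the cells were isolated by collagenase perfusion. Each of the 3 groups had 1 library. With no replicates, the differences between libraries have no replicate check, no p-value was computed, and every interval covers counting error only. How many mice a library holds, their sex, and the time of day of isolation are not given in the sources used here.

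The values analysed were UMI counts per gene and barcode in the deposited matrices, written by Cell Ranger 5.0.0 per the file headers. The genome build was mm10, per the submitters' processing notes. How the barcodes in these matrices were chosen, and aligner settings, are not given in the sources used here. Each matrix listed the same 32285 features, of which 32158 had their identifier in GENCODE release M21, which gave the chromosomes used to leave out Y-linked genes.

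The matrices held 5755 ND, 6290 HFD and 4873 HFD_HDCA barcodes with median depths of 1043, 806 and 1069 UMIs. Cells with at least 200 genes and at most 50% mitochondrial counts were retained. The retained cells were clustered together without batch integration. Counts were scaled to 10000 per cell and log-transformed, 2000 variable genes outside the mitochondrial genome were standardised with values limited to 10, and 30 principal components were taken by exact decomposition. A graph of 15 neighbours weighted by shared neighbours and the Leiden algorithm at resolution 1 with seed 0 gave 16 clusters. Software was Python 3.11.15, scanpy 1.11.5, scikit-learn 1.9.0, igraph 0.11.9, leidenalg 0.10.2, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

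The cell filters, clustering settings, marker genes, gene lists, scaling, count minimum, size rule and the rule for named genes were set before the data were examined. The scoring that turns markers into cluster names was set afterwards. The leading genes of a cluster were the 10 with the highest fold over all other cells, after adding 20 CPM, among genes detected in at least 10% of its cells. A cluster took another class if at least 3 leading genes were markers of it, more than were hepatocyte markers. It was called hepatocyte-like if at least 3 hepatocyte markers were detected in at least 10% of its cells and no other class had more leading markers. Every cluster met the detection condition, the endothelial-like, Kupffer-like and unnamed ones included. Hepatocyte-like was therefore the default name of clusters that no other class led. A cluster with none of its leading genes among hepatocyte markers and a median depth under 1/3 of its libraries' median would have stayed unnamed. The 10% condition was chosen because haemoglobin counts of a few cells otherwise led the main HFD cluster and left it unnamed. Scrublet, run per library, called 4 of 8674 retained cells doublets (0.0461%), a share too low for the caller to have worked, so doublets were not removed.

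Counts of hepatocyte-like cells were summed per library and expressed as counts per 1000000 nuclear-encoded counts (CPM). Log2 ratios of libraries were taken after adding 0.5 to each count, with 95% intervals from the exact conditional binomial. Genes with a summed count of at least 100 over the 3 libraries were measured, 7668 in all, and the size rule was a 2-fold difference. A count of 0 was read as a limit of 3 counts. The median log2 ratio over all measured genes was -0.04 for HFD against ND, 0.04 for HFD_HDCA against HFD and 0.01 for HFD_HDCA against ND. Intervals of CPM were exact Poisson and those of cell shares exact binomial.

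For each of 24 gene lists the median log2 ratio of the measured members was given with the central 95% of 200 Poisson redraws of the counts, and with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. The percentile is a description of these libraries. Mitochondrially encoded genes formed a further list, given as a share of counts. Named genes were taken by rule. For HFD against ND and for HFD_HDCA against HFD, they were the 10 highest and 10 lowest ratios among measured genes with at least 50 CPM in the higher library and at least the CPM of the other named cells, leaving out mitochondrial, ribosomal protein, unnamed gene model, Xist and Y-linked genes. Up to 4 members of each list with the largest ratios in each of these comparisons and 26 fixed genes of lipid and bile acid metabolism were added. A few genes that the rule names are not reported here. Genes outside the rule are said to be chosen after their values were seen. Counts of near-identical copies, such as the Mup, Cyp2a, Cyp2b, Cyp2c, Cyp3a, Cyp4a, Gsta, Gstm, Saa, Ugt2b and Serpina1 genes, are uncertain as to the copy.

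For shares of cells with a UMI, each cell was thinned to 500 UMIs, the 25th percentile of the shallowest library rounded down to a multiple of 100, and endothelial-like cells gave the background. The return of genes toward ND was compared with 100 simulated sets of unchanged Poisson libraries, with the overlap of independent lists, and with a repeat in which the HFD counts were split at random into parts for each comparison. For the closing section, hepatocyte-like cells with at least 1000 UMIs, thinned to that depth, were ordered within each library by 4 pericentral genes (Cyp2e1, Oat, Rgn, Cyp2c50) against 4 periportal genes (Cyp2f2, Sds, Hal, Ass1), and the outer 20% at each end were summed without thinning. Outer cells of 2 libraries were taken to hold equal positions where the summed CPM of each of these gene sets lay within 1.5 times, a limit set after the values were seen.

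The ratio, interval and list functions were tested on simulated libraries with known folds. For HFD against ND, 50 of 50 genes set 4-fold higher, 45 of 45 set 4-fold lower, 50 of 50 set 3-fold higher and 44 of 44 set 3-fold lower passed the size rule, as did 10 of 7670 unchanged genes. For HFD_HDCA against HFD, 45 of 46 genes set 3-fold lower and 7 of 7666 unchanged genes passed. The intervals held the true ratio for 95.6% and 95.5% of genes. Raised lists reached percentile 100 in each comparison, and lists of unchanged genes lay at 37.6 and 91.5.

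The alternatives set before the data were examined were at least 500 genes per cell, at most 20% mitochondrial counts or no such limit, removal of called doublets, Leiden resolutions of 0.5 and 2, all retained cells pooled, CPM of all genes, median-of-ratios size factors, a denominator without the 20 most abundant genes, the mean of per-cell CPM, thinned cells, leaving out genes higher in other named cells, and count minimums of 20 and 500. Naming without the 10% condition, removal of the 8 cells with over 1% haemoglobin counts, leaving out the cluster led by nuclear RNA, and leaving the Mup and haemoglobin genes out of the return counts were added after seeing the data. No class besides hepatocyte-like cells reached 100 cells in each library, so no ratios were computed within other classes.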

Results

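After filtering, 2776 ND, 2898 HFD and 3000 HFD_HDCA cells were retained, and hepatocyte-like cells made up 95.4% (94.6 to 96.2%), 97.9% (97.3 to 98.4%) and 97.3% (96.7 to 97.9%) of them. Hepatocyte markers were detected in every cluster, so these are shares of cells in clusters that no other class led. The largest clusters of HFD and of HFD_HDCA had 0 hepatocyte markers among their leading genes. Without the naming condition added after seeing the data, the largest HFD cluster stayed unnamed and the HFD share was 58.8%. Endothelial-like cells were 3.42% (2.78 to 4.17%) of the ND cells, 0.621% (0.369 to 0.980%) of the HFD cells and 1.13% (0.786 to 1.58%) of the HFD_HDCA cells. Kupffer-like cells, the resident macrophages of the liver, were 0.612% (0.357 to 0.979%), 0.621% (0.369 to 0.980%) and 0.867% (0.567 to 1.27%). A small cluster led by immunoglobulin and antigen presentation genes stayed unnamed, with 15, 25 and 20 cells. The hepatocyte-like cells of the 3 libraries lay mostly in separate clusters. Most barcodes of the ND and HFD libraries were rich in mitochondrial counts, with medians of 61.1% and 63.1% against 14.5% in HFD_HDCA. Mitochondrially encoded genes still took 13.8%, 13.7% and 11.1% of the counts of hepatocyte-like cells. The median depth of these cells was 944 UMIs in ND, 884 in HFD and 1127 in HFD_HDCA.

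The first comparison set the HFD library against the ND library. Cyp3a11, a drug-metabolising enzyme, was 42.2-fold lower in the HFD library, with 4559 CPM in ND and 108 in HFD (log2 ratio -5.40, 95% counting interval -5.55 to -5.26). Angptl8, a feeding-induced regulator of lipoprotein lipase, was 26.2-fold lower (interval -5.04 to -4.42), and Scd1, which desaturates fatty acids, was 2.94-fold lower. Lpin1, a phosphatidate phosphatase, was 22.4-fold higher at 992 CPM (interval 4.28 to 4.71). Cyp7a1, the rate-limiting enzyme of bile acid synthesis, was 5.54-fold higher (interval 2.23 to 2.73), and Pck1, an enzyme of gluconeogenesis, was 2.34-fold higher. Among 7668 genes, 229 were at least 2-fold higher and 210 at least 2-fold lower in HFD, against 3 and 4 in simulated unchanged libraries. The simulated libraries vary by counting error only, not by mouse or preparation. The lower count was 108 among the 3154 genes that were not higher in the other named cells. It was 101 among 4033 genes with cells thinned to equal depth, with 59 in common with the 210. Summed counts of at least 20 gave 393 and 686 of 10391 genes. With at least 500 they were 132 and 50 of 3330. The share of endothelial-like cells was lower in HFD.

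The other genes with the highest ratios were Mup17 at a log2 ratio of 4.32, Rgs16 at 4.22, Pfkfb3 at 3.97, Mfsd2a at 3.80, Mup9 at 3.37, Alas1, the first enzyme of haem synthesis, at 3.25, Onecut1 at 2.63, Coq10b at 2.60 and the clock output gene Dbp at 2.57. The other lowest ratios belonged to Gsta2 at -3.16, Csad, an enzyme of taurine synthesis, at -2.89, Tubb2a at -2.29, the lipase inhibitor G0s2 at -2.12, Slc30a10 at -1.87, Sox9 at -1.81, Efna1 at -1.66 and Etnppl at -1.63. Core clock genes, chosen after their values were seen, differed in opposite directions, with Per3 at 1.69 CPM in ND and 16.3 in HFD, and Arntl at 11.3 and 2.98.

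Genes of cholesterol synthesis and uptake were higher in HFD as a list, with 8 of 24 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.68, 0.61 to 0.88, percentile 100). Sqle, an enzyme of the pathway, had a log2 ratio of 2.04, Mvd 2.02 and Msmo1 1.77. Mvd rested on few counts, at 1.45 CPM in ND and 6.23 in HFD. Lipogenesis genes went both ways, with 3 of 20 at least 2-fold higher and 3 at least 2-fold lower (median log2 ratio -0.04, -0.13 to 0.07, percentile 27.2), and the median was -0.20 when each cell was weighted equally. Fads2 at 1.82 and Thrsp at 1.88 were higher, Acacb at -1.26 was lower, and Fasn at -0.10 and Srebf1 at -0.44 lay closer to 0. Targets of the fatty acid receptor PPARα had 4 of 31 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 0.24, 0.13 to 0.26, percentile 99.4). Ppara itself at 1.18, Cpt1a, the gate of mitochondrial fatty acid oxidation, at 1.01 and Vnn1 at 1.32 were higher, Cyp4a14 at -1.43 was lower, and Cyp4a10 at 0.03 was within 2-fold. Fatty acid oxidation enzymes had 1 of 25 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.14, 0.10 to 0.24, percentile 88.3). The lipid droplet and fatty acid uptake list had 2 of 13 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 0.00, -0.26 to 0.15, percentile 53.7, but -0.27 for the 19 with at least 20 counts), with the droplet coat genes Plin5 at 1.06 and Plin2 at -0.47. Lipoprotein genes had 1 of 19 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio -0.08, -0.09 to 0.00, percentile 23.2), with Apoa4 at 1.54.

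Genes of gluconeogenesis and insulin action were higher in HFD as a list, with 4 of 20 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.43, 0.38 to 0.52, percentile 99.99), among them Igfbp1 at 1.25 and Got1 at 1.27. Urea cycle and amino acid genes had 3 of 28 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.36, 0.32 to 0.39, percentile 99.97). Pericentral genes, which mark hepatocytes near the central vein, had 10 of 18 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 1.19, 1.08 to 1.25, percentile 100), with Gulo at 2.18, Lect2 at 1.81 and Slc1a2 at 1.76. The 14 of them that were not used to order cells along the lobule had a median of 0.99, and 0.37 within the most pericentral cells of each library. Periportal genes had 1 of 25 at least 2-fold higher and 2 at least 2-fold lower (median log2 ratio -0.10, -0.20 to -0.02, percentile 11.9). Xenobiotic metabolism genes had 4 of 26 at least 2-fold higher and 4 at least 2-fold lower (median log2 ratio 0.34, 0.26 to 0.43, percentile 99.98), with Por at 1.83 and Cyp3a59 at -2.19. Antioxidant genes had 2 of 22 at least 2-fold higher and 6 at least 2-fold lower (median log2 ratio -0.30, -0.43 to -0.12, percentile 0.13), with the metal-binding Mt1 at 1.83 and Mt2 at 2.16, and Gstm3 at -2.46. Gsta1 had 173 counts in ND and 2 in HFD (log2 ratio -5.95, interval -9.32 to -4.39). Bile acid synthesis genes other than Cyp7a1 differed less, and the list had 1 of 20 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 0.12, 0.08 to 0.19, percentile 86.5). The transporter list had 1 of 16 at least 2-fold higher and 2 at least 2-fold lower (median log2 ratio -0.10, -0.19 to 0.04, percentile 11.5), with Slco1a4 at -1.64.

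Early response and heat shock genes had 3 of 22 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.52, 0.40 to 0.60, percentile 100), with Klf6 at 2.58 and Fos at 1.38, genes that cell isolation also induces. Endoplasmic reticulum stress genes had 1 of 18 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.29, 0.20 to 0.35, percentile 99.3), with Herpud1 at 1.64. Acute phase genes had 3 of 22 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 0.14, 0.09 to 0.18, percentile 89.5), with Saa1 at 1.23. Interferon response genes had 1 of 16 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.34, 0.16 to 0.46, percentile 99.96), antigen presentation genes 0 of 12 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.25, 0.18 to 0.32, percentile 97.7), and chemokines and cytokines 1 of 6 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio -0.14, -0.28 to 0.11, percentile 24.3). Only 3 of the 16 interferon genes and 3 of the 12 antigen presentation genes were not higher in the other named cells. Male-biased genes had 6 of 23 at least 2-fold higher and 3 at least 2-fold lower (median log2 ratio 0.32, 0.25 to 0.48, percentile 99.9), and the female-biased list, with 5 of 20 genes measured, 2 at least 2-fold higher and 2 at least 2-fold lower. Genes of oxidative phosphorylation were lower by less than 2-fold, with 35 of 41 below 0 (median log2 ratio -0.24, -0.26 to -0.21, percentile 0.1), as were ribosomal protein genes, with 31 of 31 below 0 (median log2 ratio -0.34, -0.38 to -0.30, percentile 0).

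**Figure D1:**
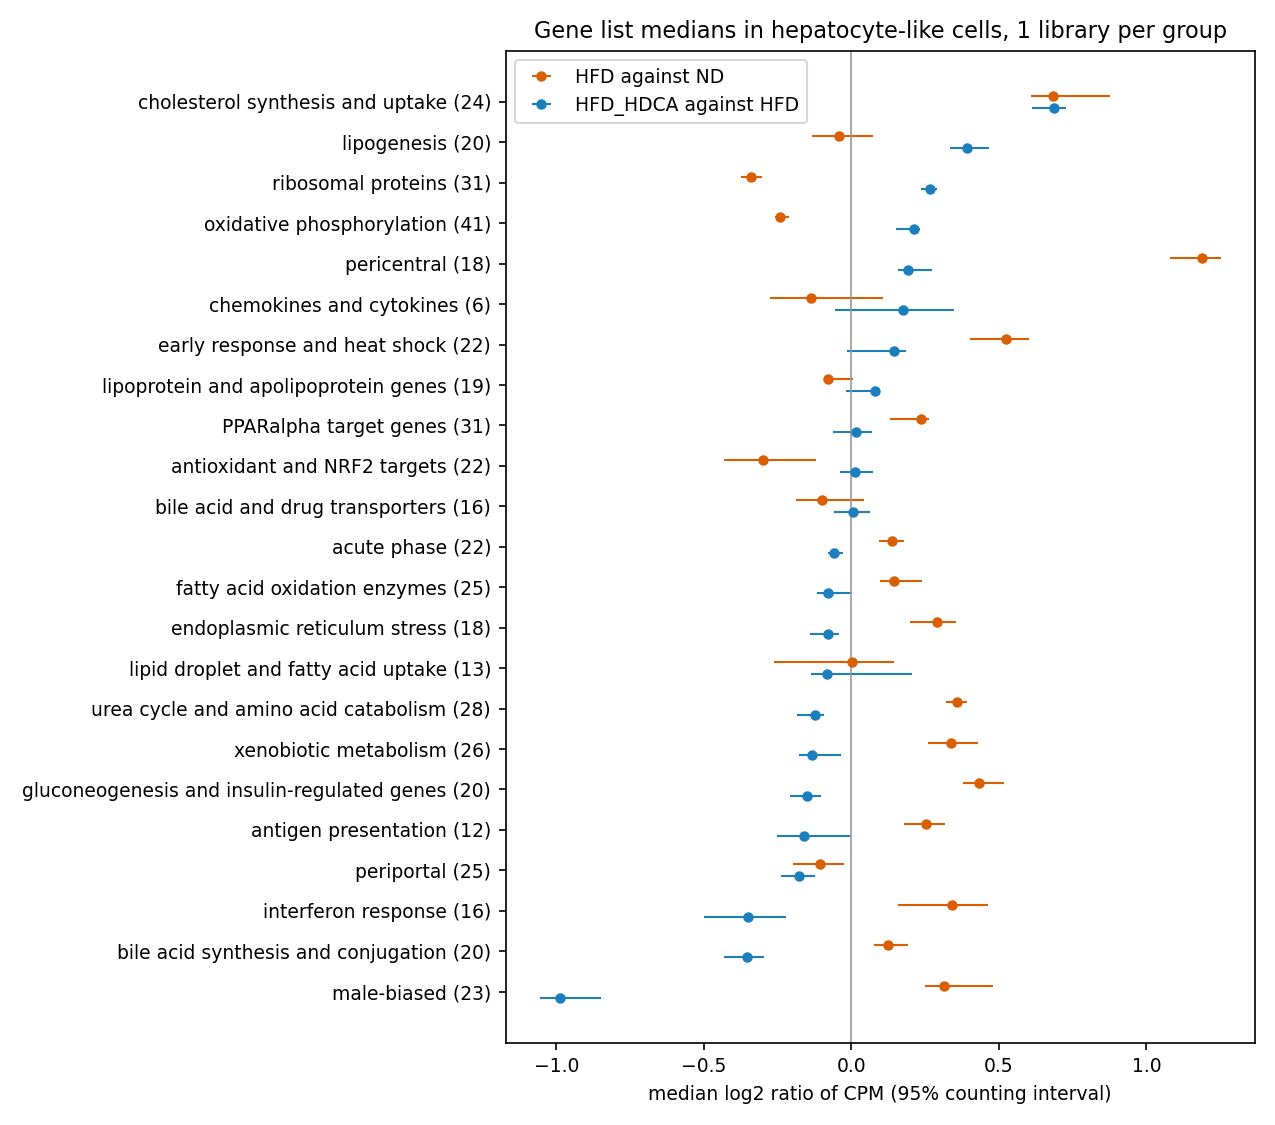
Median log2 ratio of CPM of each gene list in hepatocyte-like cells (horizontal axis) with 95% counting intervals, for HFD against ND in orange and HFD_HDCA against HFD in blue, with the number of measured genes in brackets and the female-biased list left out. The male-biased list lies at -0.99 and the cholesterol list at 0.69 for HFD_HDCA against HFD.

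The second comparison set the HFD_HDCA library against the HFD library. Cyp7a1 was 14.5-fold lower in HFD_HDCA, with 38.1 CPM in ND, 212 in HFD and 14.5 in HFD_HDCA (log2 ratio -3.86, interval -4.21 to -3.54), and Cyp2c70, which makes muricholic acids in mice, was 4.30-fold lower (interval -2.22 to -1.99). Selenbp2, a male-biased liver gene, was 149-fold lower (interval -7.99 to -6.61), and Cyp2b9, a female-biased one, was 39.3-fold higher, at 5.15 CPM in HFD and 208 in HFD_HDCA (interval 4.68 to 6.07). The PPARα target Cyp4a14 was 4.11-fold higher (interval 1.91 to 2.17) and the fatty acid transporter Cd36, which endothelial cells also express, 4.39-fold higher (interval 1.86 to 2.43). Among the measured genes, 108 were at least 2-fold higher and 111 at least 2-fold lower in HFD_HDCA, against 0 and 2 in simulated unchanged libraries, which vary by counting error only. Thinned cells gave 51 and 65 of 4033 genes, with 22 and 51 in common. Summed counts of at least 20 and 500 gave 439 and 272 of 10391, and 24 and 45 of 3330. The higher count was 61 among the 3154 genes that were not higher in the other named cells, and 172 when each cell was weighted equally.

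Other high ratios were those of Angptl8, which was 3.99-fold higher, and, as log2 ratios, Serpina7 at 1.79, G0s2 at 1.79, malic enzyme Me1 at 1.58, Rdh9 at 1.53, Csad at 1.48 and Hamp2 at 1.35. The other lowest were those of the major urinary protein genes Mup7 at -4.09, Mup9 at -3.65, Mup16 at -3.29, Mup17 at -2.97, Mup1 at -2.85, Mup14 at -2.83 and Mup18 at -2.56, and of Hsd3b5 at -2.80.

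Bile acid synthesis genes had 0 of 20 at least 2-fold higher and 3 at least 2-fold lower in HFD_HDCA (median log2 ratio -0.35, -0.43 to -0.30, percentile 0). Cyp7b1, of the alternative pathway, had a log2 ratio of -1.34, Cyp27a1 -0.92, and Cyp8b1, the sterol 12α-hydroxylase, -0.82. The bile acid receptor gene Nr1h4 at 0.29 and its target Nr0b2 at -0.50 were within 2-fold. The transporter list had 1 of 16 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 0.01, -0.06 to 0.06, percentile 39.0, but -0.12 without the naming condition), with Slco1a4 at 1.28 and Slco1a1 at -1.02. Cyp7b1 and Slco1a1 were also on the male-biased list, so their ratios are not separate from those of that list. The male-biased list had 0 of 23 at least 2-fold higher and 11 at least 2-fold lower (median log2 ratio -0.99, -1.06 to -0.85, percentile 0), and of the 20 female-biased genes 5 were measured, of which 4 were at least 2-fold higher. Cyp2b9, Acot3 and Cyp2a4 of these passed the count minimum only through the HFD_HDCA library, with 19, 14 and 1 counts in HFD, so that no median was read from this list. Cyp2a4 had 1 count in HFD and 106 in HFD_HDCA (interval 3.59 to 11.41). Y-linked genes were detected in each library, with Ddx3y, chosen after its values were seen, at 101 CPM in ND, 131 in HFD and 123 in HFD_HDCA.

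PPARα targets had 4 of 31 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.02, -0.06 to 0.07, percentile 39.3). The members at least 2-fold higher included Acot3 at 3.47, Vnn1 at 1.21 and Acot4 at 1.16, while Cyp4a10 at -0.40, Ppara at -0.41 and Cpt1a at -0.20 lay within 2-fold. Acot3, also on the female-biased list, passed the count minimum only through the HFD_HDCA library. Fgf21 and Pdk4 did not reach the count minimum, with 19, 7 and 43 counts and 20, 4 and 35 counts in ND, HFD and HFD_HDCA. Fatty acid oxidation enzymes had 0 of 25 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio -0.08, -0.12 to 0.00, percentile 3.48). Lipogenesis genes had 2 of 20 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 0.39, 0.33 to 0.47, percentile 100), with Acacb at 1.74, Acss2 at 0.94, Fasn at 0.72, Srebf1 at 0.30 and Scd1 at -0.40. All 24 measured genes of cholesterol synthesis and uptake lay above 0, with 3 of 24 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.69, 0.61 to 0.73, percentile 100), among them Mvd at 1.65 and Pmvk at 1.28. Mvd passed the count minimum only through the HFD_HDCA library. The lipid droplet and fatty acid uptake list had 2 of 13 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio -0.08, -0.14 to 0.20, percentile 8.95), with Plin2 at 0.39 and Plin5 at -1.34. Cidea and Cidec, coat genes of large droplets, did not reach the count minimum, with at most 5 counts in a library. Lipoprotein genes had 1 of 19 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.08, -0.02 to 0.10, percentile 72.2).

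Interferon response genes were lower as a list, with 15 of 16 below 0 and 0 of 16 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio -0.35, -0.50 to -0.22, percentile 0.01), among them Ifit1 at -1.16. Only 3 of the 16 were not higher in the other named cells. For HFD_HDCA against ND the list's median was -0.18, and 0.52 for these 3. Acute phase genes had 0 of 22 at least 2-fold higher and 3 at least 2-fold lower (median log2 ratio -0.06, -0.08 to -0.03, percentile 9.54), with Saa1 at -1.51 and Saa2 at -1.26. Antioxidant genes had 1 of 22 at least 2-fold higher and 2 at least 2-fold lower (median log2 ratio 0.01, -0.04 to 0.07, percentile 35.2, but -0.04 with median-of-ratios size factors), the lower ones being Mt2 at -4.28 and Mt1 at -2.23. Gluconeogenesis and insulin genes had 0 of 20 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio -0.15, -0.21 to -0.10, percentile 0.57), with Igfbp2 at -1.60 and Pck1 at -0.14. Urea cycle and amino acid genes had 0 of 28 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio -0.12, -0.18 to -0.09, percentile 0.68), with the betaine-using methyltransferase Bhmt at -1.95. Xenobiotic metabolism genes had 2 of 26 at least 2-fold higher and 2 at least 2-fold lower (median log2 ratio -0.13, -0.18 to -0.04, percentile 0.52). Pericentral genes had 1 of 18 at least 2-fold higher and 1 at least 2-fold lower (median log2 ratio 0.19, 0.16 to 0.27, percentile 97.51) and periportal genes 1 of 25 at least 2-fold higher and 2 at least 2-fold lower (median log2 ratio -0.18, -0.24 to -0.12, percentile 0.05), with Cdh1 at -3.00 and Cyp2f2 at -1.39.

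Early response genes had 1 of 22 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.14, -0.02 to 0.19, percentile 90.7, but -0.07 with thinned cells and -0.04 without genes higher in other named cells). Stress genes of the endoplasmic reticulum had 0 of 18 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio -0.08, -0.14 to -0.04, percentile 5.98). Antigen presentation genes had 0 of 12 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio -0.16, -0.25 to 0.00, percentile 1.95, but 0.19 for the 3 that were not higher in other named cells). Chemokines and cytokines had 0 of 6 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 0.18, -0.06 to 0.35, percentile 85.1). Their median was -0.20 for the 4 measured in thinned cells, -0.21 for the 4 with at least 500 counts and -0.07 with cells weighted equally. Cd1d1, which presents lipids to natural killer T cells, was at 215 CPM in ND, 231 in HFD and 266 in HFD_HDCA. Oxidative phosphorylation genes lay above 0 for 33 of 41 (median log2 ratio 0.21, 0.15 to 0.23, percentile 99.8) and ribosomal protein genes for 29 of 31 (median log2 ratio 0.27, 0.23 to 0.29, percentile 99.99), while the mitochondrially encoded share was lower in HFD_HDCA than in HFD. The median depth was also higher in HFD_HDCA.

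**Figure D2:**
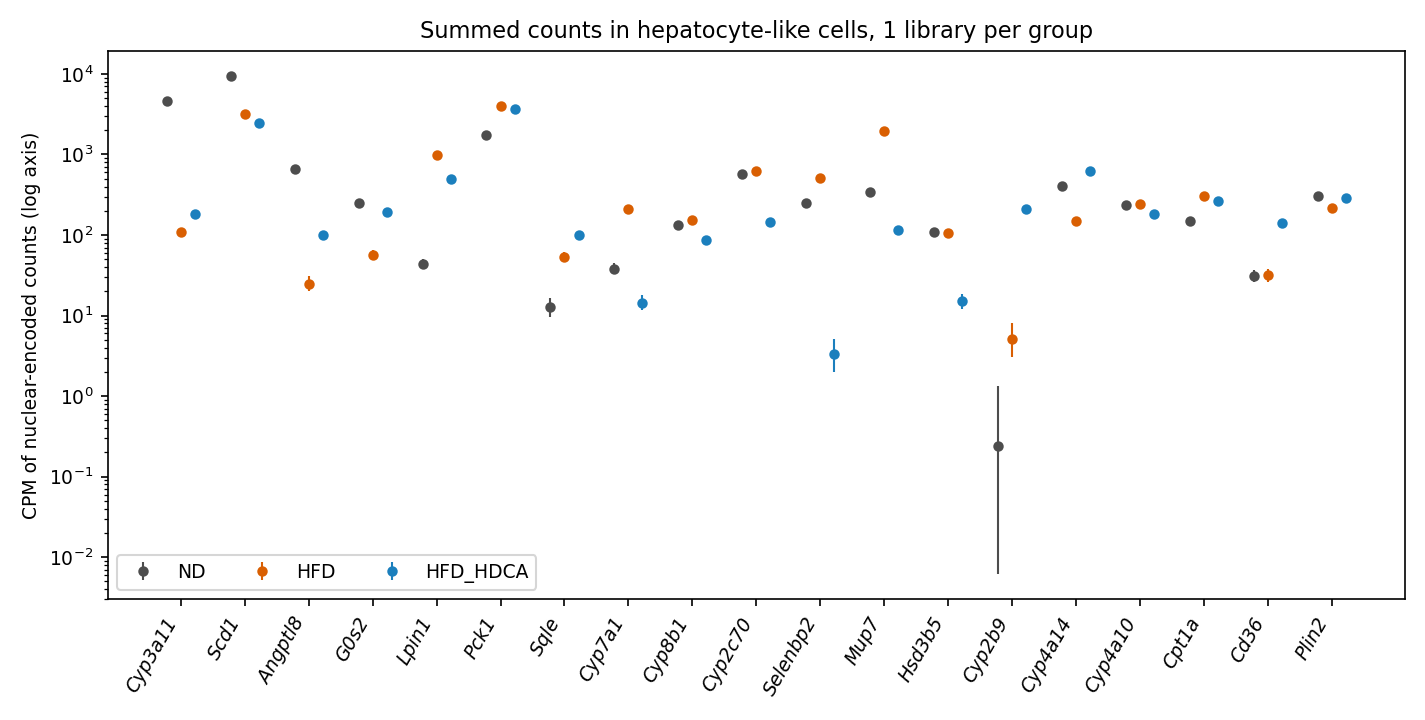
Counts per 1000000 nuclear-encoded counts (log axis) of named genes in hepatocyte-like cells of the ND, HFD and HFD_HDCA libraries, with 95% Poisson intervals. Cyp7a1 lies at 212 CPM in HFD and 14.5 in HFD_HDCA.

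Shares of hepatocyte-like cells with a UMI were taken at an equal depth of 500 UMIs, with few endothelial-like cells to give the background. Cyp4a14 was seen in 14.2% of ND, 4.50% of HFD and 19.9% of HFD_HDCA hepatocyte-like cells, against 1.05%, 0 and 0 of endothelial-like cells, with upper bounds of 5.73%, 21.8% and 10.3%. Cyp7a1 was seen in 1.85%, 8.51% and 0.616%, and in 0 thinned endothelial-like cells, with upper bounds of 3.81%, 21.8% and 10.3%. Plin2 was seen in 14.6%, 8.90% and 14.3%, against 5.26%, 20% (3 of 15 cells) and 5.88% of endothelial-like cells, with upper bounds of 11.9%, 48.1% and 19.7%. Only the Cyp4a14 shares of ND and HFD_HDCA and the Plin2 share of ND lay above these bounds, and for the other shares of these genes the background was too uncertain to say whether they lay above it. Cd36 and Glul were seen in a larger share of endothelial-like than of hepatocyte-like cells in each library, and no difference was read from their shares. Before thinning, the endothelial-like cells had median depths of 988, 632.5 and 836.5 UMIs. Cidec was seen in 1 thinned HFD_HDCA cell and in 0 of the others. The thinned shares leave out 546 HFD cells below that depth.

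**Figure D3:**
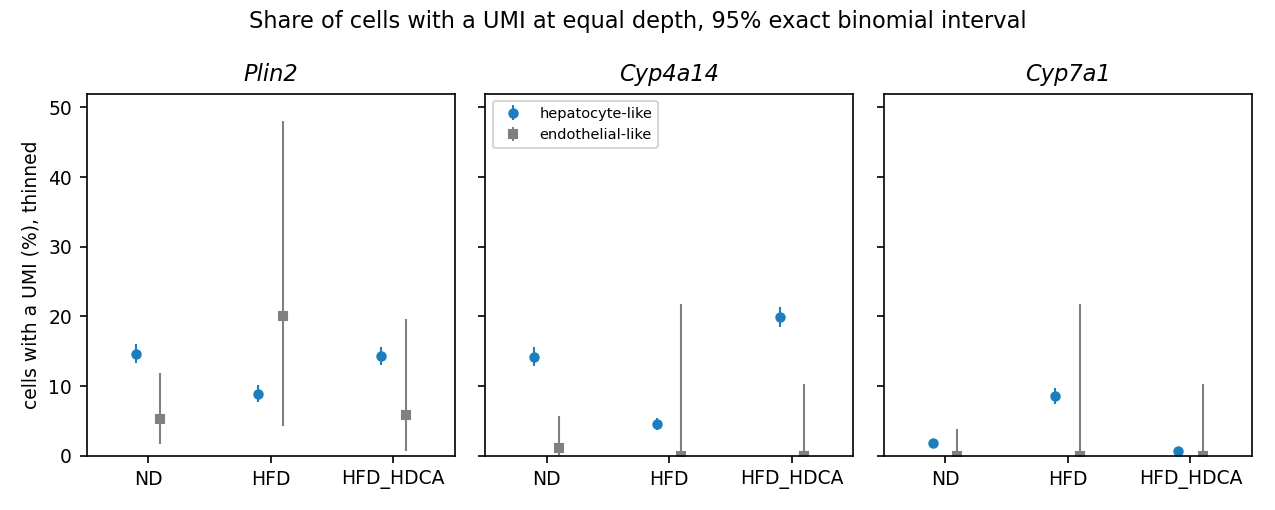
Share of cells (%) with at least 1 UMI of Plin2, Cyp4a14 or Cyp7a1 after thinning to 500 UMIs, in hepatocyte-like cells (blue circles) and endothelial-like cells (grey squares) of each library, with 95% exact binomial intervals. The Cyp7a1 share is 8.51% in HFD and 0.616% in HFD_HDCA.

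Part of the HFD difference was smaller in the HFD_HDCA library, and for some genes it turned to the opposite side of ND. Of the 229 genes at least 2-fold higher in HFD than in ND, 48 were at least 2-fold lower in HFD_HDCA than in HFD, among them Cyp7a1, Mup17 and Mt2, where independent lists would share 3.31. Some of these 48 went past ND. Against ND, HFD_HDCA had log2 ratios of -1.39 for Cyp7a1, -2.12 for Mt2 and -6.22 for Selenbp2, while Mup17 stayed higher at 1.35. Of the 48, 12 were Mup genes, near-identical copies that were not independent of each other. Without the Mup and haemoglobin genes 33 remained, against 2.67. These 48 also held the red cell genes Hbb-bs, Hba-a1 and Hba-a2, chosen after their values were seen, with Hbb-bs at 0 CPM in ND, 122 in HFD and 17.0 in HFD_HDCA and at 584 CPM in the other named cells. Retained cells with over 1% haemoglobin counts numbered 0, 6 and 2. Of the 210 lower genes, 42 were at least 2-fold higher again, among them Angptl8, G0s2 and Cyp4a14, against 2.96. Cyp2a4, also among the 42, went past ND, at 0.72 CPM in ND, 0.27 in HFD and 18.5 in HFD_HDCA. In the same direction again were 8 higher genes, including Cyp2b9, Mvd and Vnn1, against 3.23, and 6 lower genes, including Cdh1 and Cyp4a12b, against 3.04. Of the 8, Cyp2b9, Mvd and Impg2 passed the count minimum only through the HFD_HDCA library, where they were highest. The 3.23 makes no allowance for this. Mvd lay at 1.45 CPM in ND, 6.23 in HFD and 19.9 in HFD_HDCA. Still at least 2-fold from ND in HFD_HDCA were 129 of the higher genes, such as Sqle and Lpin1, and 91 of the lower ones, such as Cyp3a11 and Scd1. The correlation across genes was -0.383 and the covariance -0.0987, against -0.568 and -0.0247 in simulated unchanged libraries, since both comparisons share the HFD library. With the HFD counts split between the comparisons, 47 of 246 higher genes and 37 of 274 lower genes went back by at least 2-fold. The split removes shared counting error only. A deviation particular to the single HFD library would also appear as a return in all of these comparisons, so they cannot tell it from a return toward ND.

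Against ND, the HFD_HDCA library had 213 genes at least 2-fold higher and 191 at least 2-fold lower. Thinned cells gave 127 and 102 of 4033 genes, with 106 and 76 in common. Summed counts of at least 20 and 500 gave 417 and 512 of 10391, and 117 and 68 of 3330. Of the 3154 genes that were not higher in the other named cells, 121 were lower. Cholesterol synthesis and uptake genes had 18 of 24 at least 2-fold higher and 0 at least 2-fold lower (median log2 ratio 1.55, 1.40 to 1.61, percentile 100), and lipogenesis genes 5 of 20 at least 2-fold higher and 2 at least 2-fold lower (median log2 ratio 0.62, 0.55 to 0.68, percentile 100). PPARα targets had a median of 0.24, pericentral genes 1.21 and male-biased genes -0.85.

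No cluster of T or NK cells was found. The natural killer T cell receptor genes Trav11 and Trav11d had 0 UMIs in the retained cells of each library. This limits the share of cells with a UMI to 0.108% in ND, 0.104% in HFD and 0.1% in HFD_HDCA. With this depth and a 3′ kit it does not limit the share of cells expressing these genes. Zbtb16, which directs natural killer T cell development, was seen in 20, 90 and 82 cells, of which 20, 89 and 81 were hepatocyte-like. Klrb1c, Cxcr6, Il4, Ifng, Tbx21 and Il2rb were each seen in at most 3 cells of a library.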

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

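Tests chosen after the result was seen were those of time of day, of clock genes between the zones of 1 library, of sex, of near-identical gene copies, and of shallow cells for the pericentral genes. Erythroid markers stood out in the barcodes that the filters left out, which the comparisons do not use. In HFD_HDCA they reached 9423 CPM, 6.54-fold the 1440.4 CPM of ND (interval 6.07 to 7.06), and in HFD 616 CPM. Barcodes with over 1% haemoglobin counts numbered 2 in ND, 1 in HFD and 13 in HFD_HDCA. Among the retained hepatocyte-like cells the order was another, with Hbb-bs at 0 CPM in ND, 122 in HFD and 17.0 in HFD_HDCA. Neutrophil markers in the left-out barcodes were lower in HFD_HDCA than in ND, with 135 CPM in ND, 83.2 in HFD and 6.96 in HFD_HDCA, the last from 3 UMIs. No explanation of these differences was tested.

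Clock genes differed between the ND library and the other libraries. In HFD against ND, 9 genes that peak toward the end of the light phase had a median log2 ratio of 1.36 and 4 that peak in the opposite part of the day -1.09, with a minimum of 20 summed counts in place of 100, a difference of 2.45 (2.13 to 2.88), while for HFD_HDCA against HFD it was -0.09. The difference was 2.44 in cells with at least 500 genes, which argues against shallow cells, and 2.04 in the most periportal cells. Between the most pericentral and the most periportal cells it was -1.09 (-1.80 to 0.20) within ND and 0.21 (-0.71 to 1.37) within HFD, less than between the libraries, which with the periportal value argues against a shift in zones, while the 3.30 in the most pericentral cells decides nothing because these did not hold equal positions in ND and HFD. For HFD_HDCA against ND the 2 medians were 1.43 and -0.92. Sampling of the ND mice at another time of day or feeding state cannot be told apart from an effect of the diet on the clock. Only 1 library had the normal diet. The difference of 2.45 was also computed on a set of clock genes drawn up after clock genes had been seen to differ. Such sampling could also bear on feeding-regulated genes such as Lpin1, Angptl8 and Cyp7a1.

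Male-biased genes were lower in HFD_HDCA than in HFD, with a median log2 ratio of -0.99. Summed Y-linked genes differed by -0.17 (-0.31 to -0.06), which argues against a female or mixed sample as the source of this median. The interval leaves room for a small share of female cells. Single Y-linked genes ran from -0.08 for Uty to -0.63 for Kdm5d. Xist had 7, 1 and 3 counts in ND, HFD and HFD_HDCA. These genes were chosen after their values were seen. The list without Mup and Cyp4a12 genes had a median of -0.92 (-0.97 to -0.84), which argues against shared reads of near-identical copies. Medians of -1.21 in the most periportal and -0.93 in the most pericentral cells argue against a shift in zones. Positions were taken as equal on summed ordering genes only. Cyp2f2 alone lay at 2549 CPM in HFD and 961 in HFD_HDCA in the most periportal cells. An effect of hyodeoxycholic acid may remain as a hypothesis, found and tested on the same single pair of libraries. A difference between individual mice was not tested. With 1 library per group, a difference between cell preparations cannot be told apart from the treatment. The median mitochondrial share of barcodes was 63.1% in HFD and 14.5% in HFD_HDCA.

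Pericentral genes were higher in HFD than in ND. For the 14 genes not used to order the cells, the median log2 ratio was 0.99 in all hepatocyte-like cells and 0.37 (0.26 to 0.54) in the most pericentral cells. A larger share of pericentral cells in the HFD preparation cannot be told apart from higher expression per cell, because that interval spans the bound set for the test and the ordering did not reach equal positions, with the periportal gene Cyp2f2 at 327 CPM in the most pericentral ND cells and 20.1 in those of HFD. Shallow cells do not account for it, since the list's median was 1.19 in cells with at least 500 genes. An effect of the diet stays open and untested.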

How the results depend on the processing

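Naming without the 10% condition, removal of haemoglobin-rich cells, leaving out the nuclear RNA cluster and leaving the Mup and haemoglobin genes out of the return counts were chosen after the results were seen. No paired analysis was possible because each group had 1 library and the labels link none of them. Of the values under 15 alternatives set beforehand and 4 added ones, 89 gene counts stayed within 1.5 times and 21 did not, 1181 list medians stayed within their counting interval and 107 moved beyond it, 13 of them to the opposite sign from a median within the central 95% of random lists, and 8267 ratios of named genes stayed and 534 moved. Of 3634 alternative values for the 229 named ratios of at least 2-fold, 3540 kept their direction and size and 6 had the opposite sign. These totals include alternatives that could change little or nothing. Leiden resolution 0.5 gave the same 2649, 2837 and 2920 hepatocyte-like cells, and doublet removal took out 4 cells. Leaving genes out could not change the ratios of the genes that remained, and those 432 values all stayed. Counts of genes at least 2-fold higher and lower follow in that order. With a summed count of at least 20, which admits genes with few counts, they were 393 and 686 for HFD against ND, 439 and 272 for HFD_HDCA against HFD, and 417 and 512 for HFD_HDCA against ND. With at least 500, which leaves fewer genes, they were 132 and 50, 24 and 45, and 117 and 68. Thinned cells gave 101 lower for HFD against ND, 51 and 65 for HFD_HDCA against HFD, and 127 and 102 for HFD_HDCA against ND. Of these, 59, then 22 and 51, then 106 and 76 were among the main ones. Thinning left fewer genes past the minimum, which does not account for the genes that passed the size rule only after thinning. Leaving out genes higher in other named cells gave 108 lower for HFD against ND, 61 higher for HFD_HDCA against HFD and 121 lower for HFD_HDCA against ND. It also reversed the antigen presentation median for HFD_HDCA against HFD, to 0.19, with 3 genes left. The mean of per-cell CPM gave 172 genes higher for HFD_HDCA against HFD, a lipogenesis median of -0.20 for HFD against ND and a reversed oxidative phosphorylation median of 0.023 for HFD_HDCA against ND; the cause was not tested. Median-of-ratios factors gave a PPARα target median of 0.27 for HFD against ND, by shifting all genes. Naming without the 10% condition left 1157 HFD cells unnamed, so that hepatocyte-like cells were 58.8% of HFD, and gave a PPARα target median of 0.10 for HFD_HDCA against HFD. At least 500 genes per cell gave an ND share of 93.3%; the cause was not tested. Leaving out the nuclear RNA cluster gave shares of 93.7%, 92.5% and 93.7%, by having fewer cells. Cyp2a4, with 3 and 1 counts in ND and HFD, reversed to 0.23 with thinned cells.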

Other observations

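Genes and zones here were chosen after the values were seen. Several genes that differed between the libraries also differed along the order of cells from the portal to the central vein. Cyp2b9 reached 439 CPM in the most pericentral and 60.1 in the most periportal HFD_HDCA cells, against 11.7 and 7.59 in HFD. Cyp4a14 was also higher at the pericentral end, with 1163 against 216 CPM in ND, 239.5 against 108 in HFD and 1025 against 378 in HFD_HDCA. Cd36 lay at 429 CPM in the most pericentral HFD_HDCA cells and 7.59 in the most periportal ones, and Cyp7a1 at 399 and 10.6 in HFD. Scd1 had the opposite order in HFD, with 1919 CPM at the pericentral and 3899 at the periportal end, and in HFD_HDCA, with 1433 and 2912, but not in ND, with 10667 and 7132.

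Differences between HFD_HDCA and HFD also varied along this order. Fasn had a log2 ratio of 1.24 (0.86 to 1.66) at the pericentral and 0.41 (0.19 to 0.64) at the periportal end, and Me1 2.07 (1.66 to 2.54) and 1.07 (0.74 to 1.43). Cyp8b1 had -1.42 (-1.90 to -0.95) and -0.25 (-0.62 to 0.13). Other genes differed more at the periportal end. Cyp27a1, also of bile acid synthesis, had -0.19 (-0.53 to 0.15) at the pericentral and -1.93 (-2.62 to -1.27) at the periportal end. Hamp had -0.35 (-0.46 to -0.24) and 1.69 (1.59 to 1.80). The differences between the ends were not tested. Between HFD_HDCA and HFD the summed CPM of each ordering gene set lay within 1.5 times at both ends, the limit used for equal positions. Single genes differed more. Cyp2f2, used for the order, lay at 2549 CPM in HFD and 961 in HFD_HDCA at the periportal end. Glul lay at 394 and 950 CPM at the pericentral end. The limit on sums therefore does not establish equal positions. Between HFD and ND the ends may hold different positions. There, pericentral genes not used for the order still had a median of 0.37 for HFD against ND at the pericentral end.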
